A study of Mus musculus with 39 samples.

How the data were processed

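The data were 39 deposited tables of whole-number read counts per gene, 1 per library, from intestinal tumours and neighbouring non-tumour tissue of C57BL/6 ApcMin/+ mice. Per the labels' protocols, total RNA was purified on RNeasy columns and 500 ng was made into strand-specific libraries with the TruSeq stranded mRNA kit. Per the submitters' processing notes, Trimmomatic 0.36, TopHat2 2.0.14 and HTSeq were used with genome build GRCm38. The HTSeq version, its strand setting and the gene annotation are not given in the sources used here. The deposited counts were not normalized: they were whole numbers with a different total in each library.

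Each table held 49585 versioned gene IDs. Symbols and coordinates came from GENCODE M21 on GRCm38, which matched 49326 of these IDs; the other 259 held 0.0851% of the gene counts. The HTSeq lines that name no gene were left out of library sizes and tests. Over the libraries they held 3.00 to 13.3% (no feature), 0.203 to 0.842% (ambiguous) and 29.1 to 56.5% (not uniquely aligned) of all counts in a table. Reads that align to several places were therefore lost to the gene counts, which affects genes with near-identical copies, such as the defensins and processed pseudogenes, and makes their values uncertain.

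Gene counts per library ranged from 438639 to 11112321. The 38 libraries other than replicate 1 of wild-type non-tumour tissue held 5668185 to 11112321 counts over 20893 to 24702 genes; that library held 438639 counts over 11934 genes. At that depth 1 count was worth several CPM (counts-per-million), so its single values for genes of low abundance carry little information.

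Samples were grouped by the genotype and tissue given in the labels: wild-type Adam17 (12 tumour and 4 non-tumour libraries) and Adam17 ex/ex (17 tumour and 6 non-tumour libraries). The labels name no animal, so several samples may come from 1 animal and the p-values measure the spread between these samples. Replicate numbers were given in accession order and pair nothing. No pair of libraries within a group agreed within sampling noise: the lowest chi-square per degree of freedom over genes was 6.24 (ex/ex non-tumour, 15 pairs), 22.9 (ex/ex tumour, 136 pairs), 45.1 (wild-type tumour, 66 pairs) and 179 (wild-type non-tumour, 6 pairs). The medians were 424, 372, 364 and 600 in the same order. The lowest pairs were replicates 1 and 2, 4 and 5, 11 and 12, and 2 and 3 of these groups, each neighbours in accession order. If such close libraries share an animal, the p-values may be too small. The sex of the animals is not in the labels. Replicates 1, 2 and 3 of ex/ex tumours and 1 and 2 of ex/ex non-tumour tissue held 0.577 to 3.57 CPM of Xist and 33.9 to 44.1 CPM of Ddx3y, against 157 to 710 and 0 to 0.777 CPM in the other libraries. By these genes the former look male and all others female. Libraries that look male thus occur only in ex/ex, so sex is partly confounded with genotype. They are also consecutive in accession order.

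Differential expression was tested with edgeR 4.0.16 in R 4.3.3. All 39 libraries entered 1 quasi-likelihood fit with 4 groups, TMM factors and the filterByExpr filter, which left 16327 genes. The common dispersion was 0.188. Adjusted p-values are Benjamini-Hochberg values over these genes, with a threshold of 0.05. SE is the log2 fold change over the square root of its F statistic. The 5 contrasts were tumour against non-tumour tissue in each genotype, ex/ex against wild type in each tissue, and the interaction of both.

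Before the data were examined, 40 gene lists (signalling pathways, cell types, positions along the intestine and metabolic states) were fixed. The 39 with at least 3 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists of a contrast. Camera with an estimated correlation and fry stand beside it. A member rose or fell where its adjusted p over all genes passed the threshold; counts adjusted over the list alone stand beside. The rule for named genes was fixed at the same time: Adam17 and Apc; genes from the 12 largest and 12 smallest log2 fold changes past the threshold per contrast with an average log2 CPM of at least 1, leaving out antigen receptor segments and systematic names; up to 4 members with the smallest p of each list described; and any member of the EGFR, IL-6, STAT3, MAPK/ERK and Wnt lists. Adi1 and Kcns3, from the window around Adam17, were added outside this rule after their values were seen, and stand in the counts of named genes. Some genes chosen by the rule are not reported here; they stay in the counts. Tables for 2 further tests held the calls within 20 Mb of Adam17 on its chromosome (2-sided Fisher's exact test) and the relation of the tumour changes of both genotypes across genes.

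Alternatives fixed before the data were examined were DESeq2 1.42.0, DESeq2's size factors within edgeR, limma-voom with sample quality weights, no count filter, a stricter filter (10 counts in 23 libraries), a fit of only the groups compared, Xist as a covariate, a minimum change of 1 log2 unit, a 10 Mb window, and leaving out each library in turn. Alternatives chosen after seeing the data were limma-voom without sample weights, the mean log2 CPM of the B and plasma cell list as a covariate (the lymphoid covariate), the means of the proximal and distal small intestine lists as covariates (the position covariates), all of these together, and leaving out replicates 1 and 4 of wild-type non-tumour tissue together. The list tests, the test near Adam17 and the relation of the tumour changes without replicate 1 were also chosen then. The covariates are measured on the same libraries as the outcome.

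The fit was tested on simulated counts with 200 of 16327 genes changed. For ex/ex against wild-type tumours it recovered 34.3% of 1.5-fold, 67.2% of 2-fold and 89.4% of 4-fold changes, with 0.781% of calls false. The same shares were 13.4, 59.7 and 84.8% (2.78% false) for tumour against non-tumour tissue in ex/ex, 11.9, 38.8 and 77.3% (3.41% false) in wild type, and 7.46, 37.3 and 68.2% (5.06% false) for the genotypes in non-tumour tissue. A raised simulated list gave a camera adjusted p of 1.1e-15 in the ex/ex against wild-type tumour comparison, and 0 of 20 unchanged lists were called by camera. Genes and libraries were simulated independently, without correlation between genes or libraries that share an animal. The simulation therefore cannot show how often camera calls unchanged lists whose members move together, nor the false calls where libraries share an animal. Python 3.11 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 read the tables and drew the figures.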

Results

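Gene expression was measured by stranded mRNA sequencing in 39 libraries from intestinal tumours and neighbouring non-tumour tissue of ApcMin/+ mice, which carry a truncating mutation of Apc and develop intestinal adenomas. There were 12 tumour and 4 non-tumour libraries with wild-type Adam17, and 17 tumour and 6 non-tumour libraries homozygous for the ex allele of Adam17, known as a hypomorphic allele (ex/ex below). ADAM17 is the membrane protease that sheds EGF receptor ligands, TNF and the IL-6 receptor, and the series title names it together with EGF receptor and IL-6 trans-signalling. The libraries held 438639 to 11112321 gene counts, and 5668185 to 11112321 in the 38 libraries other than wild-type non-tumour replicate 1. In that shallow library Gm42418, a locus overlapping ribosomal RNA, took 34.8% of the counts and mitochondrial genes 21.1%. In the other libraries of its group these shares were 0.104 to 2.34% and 2.63 to 3.78%. The Gm42418 share was 0.09 to 3.52% in wild-type tumours, 0.113 to 0.267% in ex/ex tumours and 0.142 to 0.357% in ex/ex non-tumour tissue. Wild-type non-tumour replicate 4 stood apart in blood and vessel genes, with a mean log2 CPM (counts-per-million) of 7.38 for the red blood cell list and 6.52 for the endothelium list. The other 3 libraries had 2.61 to 3.14 and 3.59 to 3.92. P-values below measure the spread between samples, several of which may share an animal. Log2 fold changes are given ± SE and CPM ± SD. Adjusted p-values of genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 16327 genes.

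Adam17 (ENSMUSG00000052593.15, chromosome 12, 21323509 to 21373632 on the minus strand of GRCm38) was lower in ex/ex than in wild-type libraries of either tissue, and transcript remained in every ex/ex library. In wild-type tumours it averaged 54.7 ± 12.9 CPM (n = 12), with 86.0, 51.0, 46.6, 68.4, 38.5, 44.3, 65.2, 56.2, 48.2, 50.4, 47.5 and 54.4 CPM in the single libraries. In ex/ex tumours it averaged 23.6 ± 5.61 CPM (n = 17), with 14.5, 14.8, 15.4, 26.4, 31.2, 21.5, 22.8, 29.4, 33.5, 29.8, 24.8, 22.4, 22.9, 27.3, 21.1, 23.9 and 20.4 CPM. Adam17 in ex/ex non-tumour tissue averaged 11.1 ± 1.87 CPM (n = 6), with 10.1, 10.4, 9.95, 9.67, 14.6 and 11.6 CPM, against 42.2 ± 25.0 CPM (n = 4) in wild type, with 6.06, 48.5, 50.7 and 63.5 CPM. Against wild type it fell by 1.21 ± 0.14 on the log2 scale in tumours (adjusted p = 7.2e-08) and by 2.09 ± 0.25 in non-tumour tissue (adjusted p = 1.2e-06). The value of 6.06 CPM is 1 count, from the library labelled wild-type non-tumour replicate 1, and goes against that label. The other 15 wild-type libraries each lay above all 23 ex/ex libraries.

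**Figure D1:**
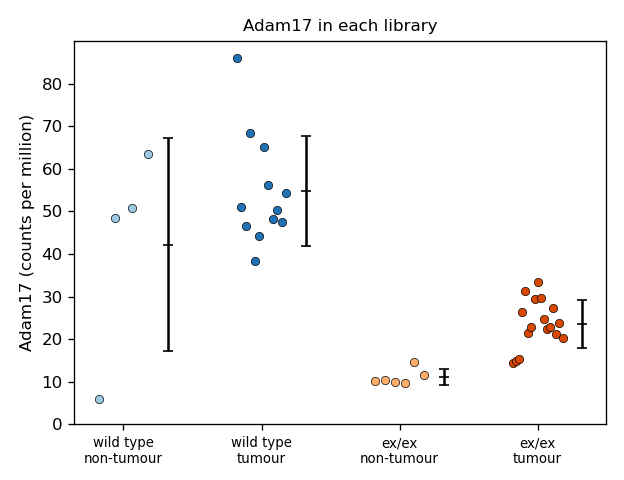
Adam17 in CPM (linear axis from 0) in each library, grouped by genotype and tissue; points are libraries, and the bars beside them show the mean ± SD. All ex/ex libraries lie between 9.67 and 33.5 CPM, and all wild-type libraries but 1 between 38.5 and 86.0 CPM.

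The comparison of wild-type tumours with wild-type non-tumour tissue asked what sets an ApcMin/+ adenoma apart from its surroundings. The Wnt pathway transcription factor Lef1, which T cells also express, rose by a log2 fold change of 3.23 ± 0.78 (adjusted p = 0.010). The secreted Wnt inhibitors Wif1 (3.84 ± 1.04, adjusted p = 0.023) and Dkk2 (1.84 ± 0.52, adjusted p = 0.029) rose too. Notum, a Wnt-inhibiting lipase made by Apc-mutant cells, averaged 70.8 ± 70.8 CPM in tumours (n = 12) and 8.02 ± 9.54 in non-tumour tissue (n = 4), with an adjusted p of 0.20. The ileal bile acid-binding protein Fabp6 went from 9.66 ± 13.8 to 1773 ± 1590 CPM. Reg1, a regenerating protein of the proximal gut, went from 146 ± 40.3 to 6.93 ± 6.45 CPM. The stem cell gene Olfm4 (-2.32 ± 0.50) and Neurog3, the transcription factor of enteroendocrine progenitors (-2.60 ± 0.49), fell, as did Cyp4a10, a PPAR-alpha target (-4.56 ± 0.98). The sulfotransferase gene Sult6b2 (-4.72 ± 0.84) and Bbox1, an enzyme of carnitine synthesis (-4.57 ± 0.92), fell too.

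In all, 825 of 16327 genes were called in wild-type tumours (310 higher, 515 lower). Of 21 Wnt/beta-catenin targets 3 rose and 0 fell by edgeR (6 and 0 adjusted over the list alone), and 18 missed the threshold. Camera did not call this list (adjusted p = 0.0795, and 0.972 with an estimated correlation). Camera called 5 lists, and each had an adjusted p = 0.972 with an estimated correlation. Of 11 endothelial genes 7 fell (9 adjusted over the list alone, camera adjusted p = 0.00915), among them Tek (-1.89 ± 0.31), Kdr (-2.23 ± 0.39), Vwf (-1.93 ± 0.36) and Emcn (-1.53 ± 0.36). These endothelial calls all ended without non-tumour replicate 4, the library rich in vessel and blood genes. Tek then stood at -0.61 (adjusted p = 0.23), Kdr at 0.11 (0.88), Vwf at -0.02 (0.99) and Emcn at -0.15 (0.85). Of 24 enterocyte genes 1 fell (0 adjusted over the list alone, camera adjusted p = 9.9e-04), and of 14 macrophage and dendritic cell genes 2 fell (1 rose and 8 fell adjusted over the list alone, camera adjusted p = 9.9e-04). Of 12 PPAR-alpha genes 1 fell (4 adjusted over the list alone, camera adjusted p = 0.00153), and of 13 cholesterol synthesis genes 1 rose (3 adjusted over the list alone, camera adjusted p = 0.0366). The members concerned were Cyp3a11 (-2.27 ± 0.70), the macrophage genes Adgre1 (-1.45 ± 0.36) and Ms4a7 (-1.14 ± 0.31), Cyp4a10, and Srebf2, the regulator of cholesterol synthesis (0.73 ± 0.22). Camera no longer called the cholesterol list without non-tumour replicate 1 (adjusted p = 0.111), nor the enterocyte (0.0644) and PPAR-alpha (0.0548) lists with the mean of the B and plasma cell list as a covariate (the lymphoid covariate). That covariate brought a call of Wnt targets as higher (0.00956), and leaving out replicate 1 brought calls of enteroendocrine genes as lower (6.9e-04) and inflammatory genes as higher (0.0106). None of these 3 calls held, with adjusted p = 0.809, 0.909 and 0.909 with an estimated correlation. The EGFR family (10), MAPK/ERK response (17), STAT3 response (17) and IL-6 family (11) lists had 0 members past edgeR's threshold in either direction (0, 0, 0 and 1 adjusted over the list alone).

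Other genes called in wild-type tumours were Duox2, an oxidase of the mucosal surface (3.16 ± 0.82), and the absorptive-cell genes Plb1 (8.31 ± 2.29) and Tmigd1 (5.94 ± 1.54), all higher. So were Slc38a4, an amino acid transporter (5.68 ± 1.5), the follicular B cell gene Cr2 (6.86 ± 2.10) and Tnfaip3, an inhibitor of NF-kB (0.86 ± 0.23). The Paneth cell genes Lyz1 (-1.72 ± 0.52) and Defa26 (-2.54 ± 0.67, a member of a gene family whose copies share reads) and the hormone gene Ghrl (-2.01 ± 0.60) were lower. Apc itself (ENSMUSG00000005871.14, chromosome 18, 34220924 to 34322552) fell from 162 ± 18.2 to 112 ± 19.6 CPM (-0.52 ± 0.14, adjusted p = 0.019). The calls of Cyp4a10, Neurog3, Sult6b2, Bbox1 and Reg1 held without any 1 library. The call of Lef1 ended without non-tumour replicate 2 (adjusted p = 0.067) and that of Wif1 without replicate 2 (0.11) or 4 (0.057). The same held for Olfm4 without replicate 2 (0.055) and for Dkk2 without replicate 2, 3 or 4 (0.054 to 0.11). Without replicate 4 the calls of Adgre1 (0.17) and Ms4a7 (0.51; also without tumour replicate 8, 0.052) ended. Lars2 (-4.13 ± 0.61), mt-Rnr2 (-3.72 ± 0.56) and Pnck (-6.41 ± 0.78) were called lower, but without the library labelled wild-type non-tumour replicate 1 they stood at -0.15, -0.12 and 0.78 (adjusted p = 0.89, 0.91 and 0.32). Calls that ended without single non-tumour libraries were those of Apc (replicates 1 and 2, 0.065 and 0.088), Duox2 (1 and 2, 0.054 and 0.074), Defa26 (2 and 3, 0.19 and 0.094), and Slc38a4 (2 and 3, 0.088 and 0.061). So were those of Plb1 (1 to 4, 0.055 to 0.080), Tmigd1 (2 to 4, 0.054 to 0.059) and Tnfaip3 (1, 2 and 4, 0.062 to 0.070). Those of Cr2, Ghrl, Lyz1, Cyp3a11, Srebf2 and Fabp6, all near the threshold, ended without any 1 of 8 to 13 libraries (0.050 to 0.42). Of 31 called genes chosen by the naming rule, 10 kept the call without replicates 1 and 4 of non-tumour tissue. Of the 30 tested in a fit of only the 2 groups, 13 did. With the lymphoid covariate 31 of the 31 kept the call, and with the position covariates 23 did. The position covariates ended the calls of Cr2, Dkk2, Duox2, Emcn, Fabp6, Ghrl, Plb1 and Srebf2, and 3 of the 7 endothelial genes still fell. Fabp6 belongs to the distal list, from which a position covariate was made, so the loss of its call was partly built in. The proximal transcription factors Gata4, Pdx1 and Onecut2 were not called in wild type (adjusted p = 0.39, 0.88 and 0.80). Whether a difference in position between wild-type tumours and non-tumour tissue bears on the other calls stays open.

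The same comparison in ex/ex asked what sets these tumours apart from their surroundings, and among the genes higher in tumours were many of B cells. Cr2 rose from 1.5 ± 1.42 CPM (n = 6) to 279 ± 131 CPM (n = 17). Ms4a1, which encodes CD20, rose from 1.84 ± 1.35 to 412 ± 225 and the B cell transcription factor Pax5 from 0.762 ± 0.707 to 220 ± 118. The MHC class II genes Cd74 (2.29 ± 0.49), H2-Aa (2.16 ± 0.49) and their regulator Ciita (3.55 ± 0.81) rose, and so did Tnf (3.94 ± 0.67). The stem cell genes Olfm4 (-3.49 ± 0.41), Slc12a2 (-2.23 ± 0.27), Lrig1 (-1.42 ± 0.18) and Smoc2 (-1.90 ± 0.33) fell. Genes of the stomach and duodenum were among the largest falls, with the duodenal transcription factor Pdx1 (-7.93 ± 0.82, adjusted p = 6.0e-09), the alkaline phosphatase Akp3 (-9.92 ± 0.79) and enteropeptidase (Tmprss15, -9.74 ± 0.87). The gastric-type genes Tff2 (-12.11 ± 1.5), Muc6 (-11.36 ± 1.43) and Gkn3 (-10.54 ± 1.30) also fell. The size of these 3 rested on ex/ex non-tumour replicate 4, without which Tff2 stood at -2.85 (adjusted p = 0.015), Muc6 at -2.72 (0.026) and Gkn3 at -2.69 (0.011).

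In ex/ex 7685 genes were called (3885 higher, 3800 lower), and camera called 13 lists, none of them with an estimated correlation. Of 14 B and plasma cell genes 10 rose and 3 fell (the same numbers adjusted over the list alone; camera adjusted p = 0.00374, and adjusted p = 0.71 with an estimated correlation). All 9 MHC class II genes rose (9 adjusted over the list alone; 4.0e-05, and adjusted p = 0.689 with an estimated correlation). So did 8 of 13 inflammatory and NF-kB genes, with 1 lower (8 and 1 adjusted over the list alone; 0.0192, and adjusted p = 0.71 with an estimated correlation). Among them were the adhesion molecule Icam1 (2.61 ± 0.63) and Tnfaip3 (0.86 ± 0.18). Of 20 proliferation genes 9 rose (10 adjusted over the list alone; 0.0211, and adjusted p = 0.787 with an estimated correlation). They included the replication genes Mcm3 (1.85 ± 0.41) and Mcm4 (1.57 ± 0.36). Of 13 cholesterol synthesis genes 6 rose and 1 fell (8 and 1 adjusted over the list alone; 0.0431, and adjusted p = 0.711 with an estimated correlation), with Srebf2 at 1.02 ± 0.19. With the lymphoid covariate, 0 of the 9 class II, 2 of the 8 inflammatory, 0 of the 9 proliferation and 6 of the 6 cholesterol genes still rose.

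Among the lists lower in ex/ex tumours, 10 of 12 stem cell genes (10 adjusted over the list alone), 10 of 12 PPAR-alpha genes (11) and 9 of 11 endothelial genes (9) fell. Camera gave adjusted p-values of 4.0e-05, 1.2e-05 and 4.0e-05, and each list had an adjusted p = 0.54 with an estimated correlation. PPAR-alpha genes that fell included the thioesterase Acot1 (-3.01 ± 0.34) and Cyp4a10 (-5.17 ± 0.69). Vessel genes that fell were Lyve1 (-1.81 ± 0.21), Tek (-1.75 ± 0.25) and Kdr (-2.03 ± 0.32). Of 15 enteroendocrine genes 11 fell and 1 rose (11 and 1 adjusted over the list alone; 5.2e-04, and adjusted p = 0.71 with an estimated correlation). Among them were the hormone genes Cck (-2.89 ± 0.34) and Ghrl (-3.97 ± 0.47) and Neurog3 (-3.11 ± 0.37). Of 12 Paneth cell genes 9 fell (9 adjusted over the list alone; 0.0214, and adjusted p = 0.71 with an estimated correlation). Examples were Lyz1 (-2.75 ± 0.42) and Defa30 (-2.71 ± 0.55, again from a family that shares reads). Of 12 genes of enteric neurons and glia 10 fell (11 adjusted over the list alone; 0.0109, and adjusted p = 0.71 with an estimated correlation). The neuropeptide gene Vip was at -3.12 ± 0.46 and the glial gene S100b at -2.77 ± 0.47. Of 24 enterocyte genes 7 fell (4 adjusted over the list alone; 0.00621, and adjusted p = 0.759 with an estimated correlation). Of 9 genes of the proximal small intestine 7 fell (8 adjusted over the list alone; 6.5e-04, and adjusted p = 0.54 with an estimated correlation), including the iron exporter Slc40a1 (-4.29 ± 0.57). Of 10 distal genes 5 rose and 1 fell (5 and 1 adjusted over the list alone), with Fabp6 at 6.81 ± 1.86, and camera did not call them (adjusted p = 0.0866). With the lymphoid covariate 3 of the 10 stem cell, 4 of the 10 PPAR-alpha, 9 of the 9 endothelial, 3 of the 11 enteroendocrine, 1 of the 9 Paneth, 3 of the 10 neural, 0 of the 7 enterocyte and 4 of the 7 proximal genes still fell. The same counts with the position covariates were 4, 4, 5, 5, 7, 1, 0 and 1. Of 45 called genes chosen by the naming rule for ex/ex tumours against non-tumour tissue, 35 kept their call with the lymphoid covariate, which ended, among others, those of Cd74, Ciita, H2-Aa, Icam1, Mcm3, Mcm4, Smoc2, Defa30 and Ephb2. With the position covariates 29 did, and with both kinds Fabp6 stood at -0.77. Fabp6 and the proximal genes are members of the lists that made the position covariates, so the loss of their calls was partly built in. Camera with the lymphoid covariate no longer called the B and plasma cell (adjusted p = 0.913), class II (0.202), inflammatory (0.0952), proliferation (0.218), enteroendocrine (0.164), Paneth (0.433), neural (0.202) and enterocyte (0.167) lists. It then called as higher the regenerative (3.7e-04), STAT3 response (3.7e-04), immediate early (8.1e-04), distal (0.00348), MAPK/ERK (0.0104) and smooth muscle (0.0307) lists, with adjusted p = 0.455, 0.213, 0.213, 0.509, 0.509 and 0.846 with an estimated correlation. As lower it called macrophages and dendritic cells (1.6e-05), fibroblasts (0.00218), T and NK cells (0.0311) and interferon response (0.0311), with adjusted p = 0.385, 0.509, 0.509 and 0.765 with an estimated correlation.

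Wnt targets went both ways in ex/ex tumours. Of 21, 3 rose and 9 fell (3 and 9 adjusted over the list alone), and camera did not call them (adjusted p = 0.204; 0.787 with an estimated correlation). Lef1 (3.84 ± 0.60) and Tcf7 (3.02 ± 0.58), which T cells also express, rose, and Ephb2 (-1.59 ± 0.26) and Bmp4 (-1.38 ± 0.27) fell. Notum averaged 0.653 ± 1.77 CPM in ex/ex tumours and 1.58 ± 1.65 in ex/ex non-tumour tissue. Socs3, a feedback inhibitor induced by STAT3, rose from 11.4 ± 1.64 to 27.9 ± 5.67 CPM (1.30 ± 0.14, adjusted p = 1.9e-08). Of 17 STAT3 response genes 5 rose and 1 fell (5 and 1 adjusted over the list alone), and camera did not call them (adjusted p = 0.128). Apc fell from 148 ± 16 to 95.3 ± 15.2 CPM (-0.63 ± 0.11, adjusted p = 3.8e-05).

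**Figure D2:**
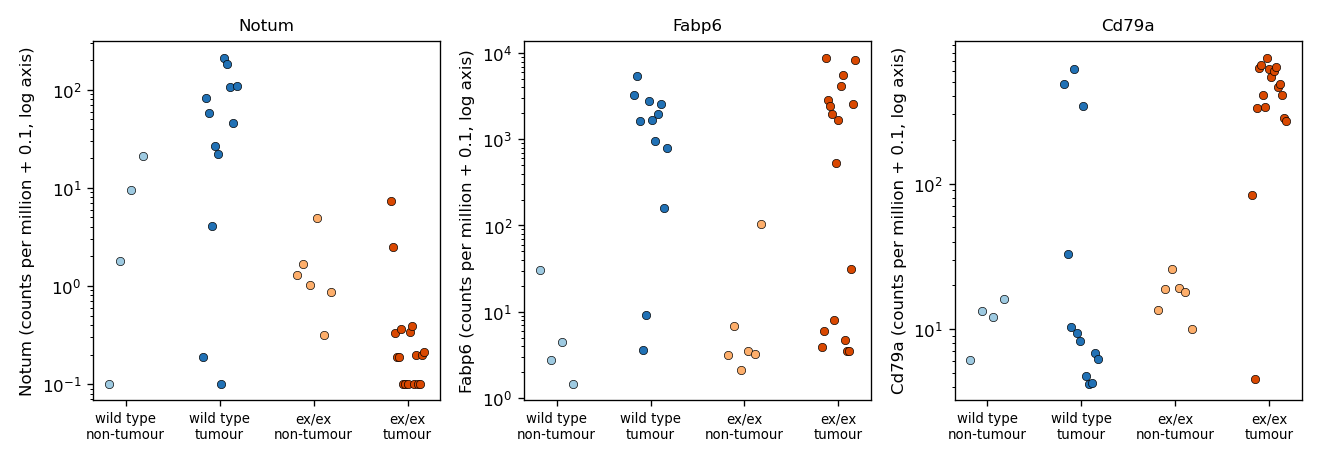
Notum, Fabp6 and Cd79a in each library by genotype and tissue, in CPM plus 0.1 on log axes; each point is 1 library. Notum reached 213 CPM in wild-type tumours and at most 7.17 CPM in ex/ex tumours, while Cd79a exceeded 25.8 CPM, the highest value of non-tumour tissue, in most ex/ex and few wild-type tumours.

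The comparison of ex/ex with wild-type tumours asked how tumours differ where ADAM17 is reduced, and Wnt target and stem cell genes were lower in ex/ex. Notum averaged 70.8 ± 70.8 CPM in wild-type (n = 12) and 0.653 ± 1.77 CPM in ex/ex tumours (n = 17). Wif1 (-5.44 ± 0.56), the Wnt feedback inhibitor Nkd1 (-4.01 ± 0.45), the transcription factor Prox1 (-3.95 ± 0.42) and Dkk2 (-2.50 ± 0.28) fell. Axin2, the common readout of Wnt activity, fell by 1.18 ± 0.22 (adjusted p = 1.1e-04). Of 21 Wnt targets 16 fell and 0 rose by edgeR (16 and 0 adjusted over the list alone; camera adjusted p = 4.6e-09, and adjusted p = 0.198 with an estimated correlation). Of 12 stem cell genes 8 fell (8 adjusted over the list alone; 0.00135, and adjusted p = 0.36 with an estimated correlation), among them Lgr5 (-2.72 ± 0.40), Tnfrsf19 (-2.55 ± 0.32), Sox9 (-2.39 ± 0.35) and Msi1 (-1.59 ± 0.23). In the same libraries the B cell receptor gene Cd79a averaged 441 ± 204 CPM in ex/ex and 127 ± 221 CPM in wild-type tumours. With the lymphoid covariate 10 of the 16 Wnt targets and 1 of the 8 stem cell genes still fell, and with the position covariates 12 and 6. Axin2 lost its call with either, and Lgr5, Sox9 and Msi1 lost theirs with the lymphoid covariate.

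Several genes of the growth factor pathways named in the series title were lower in ex/ex tumours. The EGF receptor gene Egfr (-1.41 ± 0.27, adjusted p = 9.8e-05) and its ligands betacellulin (Btc, -2.02 ± 0.34), amphiregulin (Areg, -2.10 ± 0.36), epiregulin (Ereg, -1.21 ± 0.35) and transforming growth factor alpha (Tgfa, -0.79 ± 0.29, adjusted p = 0.035) fell, with Nrg1, a ligand of ERBB3 and ERBB4 (-1.45 ± 0.25). These are 6 of 10 EGFR family genes, with 0 higher by edgeR (6 and 0 adjusted over the list alone; camera adjusted p = 0.0129, and adjusted p = 0.494 with an estimated correlation). Of 17 MAPK/ERK response genes 15 fell (15 adjusted over the list alone; 2.5e-08, and adjusted p = 0.198 with an estimated correlation). They included Phlda1 (-3.16 ± 0.32), the ETS factor Etv5 (-2.39 ± 0.28), the AP-1 subunit Fosl1 (-5.24 ± 0.64) and Ier3 (-2.23 ± 0.27). Given the lymphoid covariate, 1 of the 6 EGFR family and 7 of the 15 MAPK/ERK genes still fell (1 and 9 with the position covariates). Areg, Btc, Egfr, Ereg and Tgfa lost their calls with either, and Tgfa stood at 0.35 with the lymphoid and 0.34 with the position covariates. The call of Tgfa also ended (adjusted p = 0.051 to 0.060) without any 1 of 13 libraries. These were replicates 2, 3, 5, 6 and 10 to 12 of wild-type and 4, 5, 8 to 10 and 12 of ex/ex tumours. Against non-tumour tissue of ex/ex, the median Wnt target stood at -0.85 and the median pan-epithelial marker at -0.42 in ex/ex tumours. A smaller share of adenoma epithelium in ex/ex than in wild-type tumour libraries therefore stays open. It was not tested for these genes or for the STAT3, matrix and regenerative genes below.

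IL-6 itself (Il6) averaged 0.662 ± 0.732 CPM in wild-type and 0.281 ± 0.154 CPM in ex/ex tumours (-1.07 ± 0.45, adjusted p = 0.063). Il6 was tested in 25 of the 29 fits that left out 1 tumour library, and passed the threshold in 4 of them, without replicate 1, 3, 5 or 6 of wild-type tumours (0.033 to 0.047). Of 11 IL-6 family genes 2 fell and 0 rose by edgeR (2 and 0 adjusted over the list alone; camera adjusted p = 0.934). Il11 went from 5.95 ± 6.65 to 0.262 ± 0.117 CPM (-4.43 ± 0.55, adjusted p = 1.7e-07) and Lif fell by 0.72 ± 0.18 (adjusted p = 0.0021). Of 17 STAT3 response genes 7 fell and 1 rose (10 and 1 adjusted over the list alone; camera adjusted p = 0.00397, and adjusted p = 0.239 with an estimated correlation). The largest were the siderophore-binding protein Lcn2 (39.9 ± 48.7 to 0.656 ± 0.267 CPM, -5.92 ± 0.63), Lrg1 (-4.08 ± 0.48), the acute phase gene Saa3 (-3.29 ± 0.46) and Timp1 (-3.23 ± 0.44), and Socs3 fell by 0.67 ± 0.10 (adjusted p = 5.3e-06). Of the 7 STAT3 genes 4 still fell with the lymphoid covariate, and Il11, Lif and Saa3 lost their calls. With the position covariates 5 did, and Lif lost its call. The inflammatory and NF-kB list went both ways (3 of 13 higher and 5 lower, 4 and 5 adjusted over the list alone; camera adjusted p = 0.694). The neutrophil chemokine genes Cxcl1 (-3.46 ± 0.51), Cxcl2 (-3.89 ± 0.55) and Cxcl5 (-3.70 ± 0.48) and the prostaglandin synthase Ptgs2 (-2.59 ± 0.34) fell. Of the inflammatory genes 1 of 3 still rose and 3 of 5 still fell with the lymphoid covariate, and 3 and 3 with the position covariates; Cxcl1 lost its call with either.

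Invasion, regeneration and stroma genes were also lower in ex/ex tumours. Of 13 matrix remodelling genes 11 fell (11 adjusted over the list alone; camera adjusted p = 5.3e-07, and adjusted p = 0.225 with an estimated correlation). Examples were the protease Mmp14 (-1.57 ± 0.23) and the urokinase receptor Plaur (-1.77 ± 0.26). Of 13 genes of regenerative or fetal-like epithelium 10 fell and 1 rose (10 and 1 adjusted over the list alone; 1.6e-05, and adjusted p = 0.211 with an estimated correlation). They included Anxa1 (-3.19 ± 0.38), Anxa3 (-1.82 ± 0.24) and the alarmin Il33 (-1.74 ± 0.22). All 10 mast cell genes fell (10 adjusted over the list alone; 6.4e-07, and adjusted p = 0.239 with an estimated correlation). Among them were the mast cell proteases Tpsb2 (-5.53 ± 0.67), Cma1 (-5.82 ± 0.76) and Cpa3 (-4.41 ± 0.64) and the transcription factor Gata2 (-2.24 ± 0.30). When the lymphoid covariate was added, 4 of the 11 matrix, 5 of the 10 regenerative and 3 of the 10 mast cell genes still fell, and with the position covariates 9, 6 and 2. All 5 red blood cell genes fell (5 adjusted over the list alone; 4.6e-09, and adjusted p = 0.123 with an estimated correlation), with Hbb-bt, Hbb-bs and Hba-a1 at -4.21 ± 0.41, -4.23 ± 0.43 and -4.58 ± 0.47. So did 9 of 11 endothelial genes (10 adjusted over the list alone; 1.9e-05, and adjusted p = 0.24 with an estimated correlation), with Vwf at -1.34 ± 0.25. Of 14 fibroblast genes 8 fell (1 rose and 9 fell adjusted over the list alone; 0.00626, and adjusted p = 0.487 with an estimated correlation). They included fibronectin (Fn1, -1.70 ± 0.25) and Col1a1 (-1.43 ± 0.22). Under the lymphoid covariate 5 of the 5 red blood cell, 8 of the 9 endothelial and 6 of the 8 fibroblast genes still fell.

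Some metabolic, muscle and neural genes were lower too. Of 13 hypoxia and glycolysis genes 8 fell in ex/ex tumours (8 adjusted over the list alone; camera adjusted p = 8.3e-06, and adjusted p = 0.239 with an estimated correlation). Examples were the glucose transporter Slc2a1 (-1.55 ± 0.22) and hexokinase 2 (Hk2, -1.29 ± 0.21). Of 13 cholesterol synthesis genes 10 fell (11 adjusted over the list alone; 6.7e-04, and adjusted p = 0.487 with an estimated correlation). They included Fdft1 (-1.12 ± 0.20) and Idi1 (-0.67 ± 0.14). Of 12 smooth muscle genes 5 fell (6 adjusted over the list alone), as did 4 of 12 neural genes (6) and 4 of 9 proximal small intestine genes (4). Camera gave adjusted p-values of 0.00313, 0.0114 and 0.0177, and adjusted p = 0.556, 0.556 and 0.487 with an estimated correlation. Given the lymphoid covariate, 3 of the 8 hypoxia, 0 of the 10 cholesterol, 0 of the 5 smooth muscle, 1 of the 4 neural and 0 of the 4 proximal genes still fell. Camera then called none of these 5 lists (adjusted p = 0.468, 0.14, 0.912, 0.676 and 0.902).

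Several B cell, class II and proliferation genes were higher in ex/ex tumours. Of 14 B and plasma cell genes 4 rose by edgeR (6 rose and 1 fell adjusted over the list alone; camera adjusted p = 2.6e-06, and adjusted p = 0.36 with an estimated correlation). They were the plasma cell gene Mzb1 (1.30 ± 0.46), Pou2af1 (1.95 ± 0.70), Cd79a (1.79 ± 0.69) and Cr2 (2.10 ± 0.82). The calls of Cr2, Cd79a, Pou2af1 and Mzb1 are near the threshold and ended (adjusted p = 0.050 to 0.078) without any 1 of 22, 18, 7 and 3 libraries. These lie among replicates 2, 3, 5, 6 and 8 to 12 of wild-type and 4 to 15 and 17 of ex/ex tumours. Of 9 MHC class II genes 8 rose (9 adjusted over the list alone; 9.4e-07, and adjusted p = 0.239 with an estimated correlation), including Ctss (0.46 ± 0.10), H2-DMa (1.14 ± 0.31) and H2-Ab1 (1.08 ± 0.30). Of 15 T and NK cell genes 1 rose (1; 0.0023, and adjusted p = 0.487 with an estimated correlation), and with the lymphoid covariate camera called this list lower (0.00811, and adjusted p = 0.379 with an estimated correlation). Of 20 proliferation genes 9 rose (13 adjusted over the list alone; 0.00746, and adjusted p = 0.678 with an estimated correlation). Among them were Mcm6 (1.23 ± 0.26), Pcna (0.74 ± 0.16) and Mki67 (1.03 ± 0.30). Under the lymphoid covariate 1 of the 8 class II and 0 of the 9 proliferation genes still rose, and Mzb1 (-0.25) and Mki67 (-0.13) had the other sign. Camera then called neither list (adjusted p = 0.662 and 0.0904), nor that of B and plasma cells, from which the covariate was made (0.902).

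**Figure D3:**
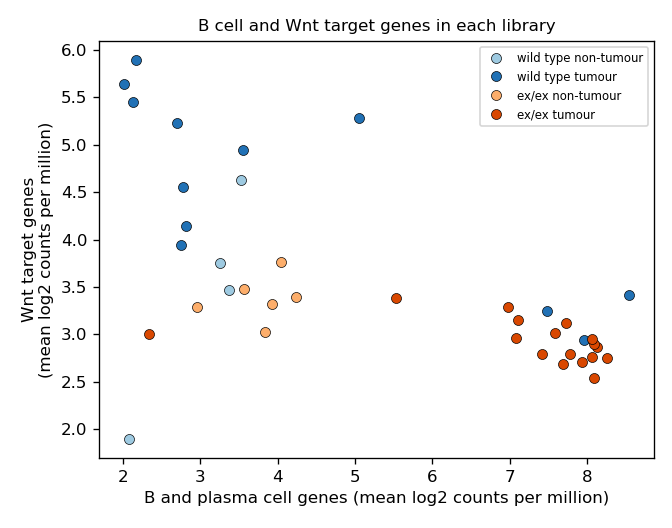
Mean log2 CPM of the B and plasma cell list (horizontal axis) and of the Wnt target list (vertical axis) in each of the 39 libraries, coloured by genotype and tissue. Wnt targets ranged from 2.94 to 5.89 in wild-type tumours and from 2.54 to 3.38 in ex/ex tumours, most of which lay on the right, as did 3 wild-type tumours.

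In total 5429 genes differed between ex/ex and wild-type tumours (2488 higher, 2941 lower), and camera called 20 lists, none of them with an estimated correlation. The Gm42418 share of the counts also differed here, with a median of 0.159% in ex/ex and 0.968% in wild-type tumours, and was not adjusted for. Genes higher in ex/ex included Cyp1a1, the target of the aryl hydrocarbon receptor (0.516 ± 0.582 to 7.90 ± 3.52 CPM), Map3k19 (5.50 ± 0.75), the nuclear receptor Nr0b2 (3.25 ± 0.43) and the lectin receptor Clec4e (2.86 ± 0.52). Genes lower included Wfdc18 (-10.35 ± 1.29), albumin (Alb, -8.78 ± 0.99), Slc38a4 (-8.34 ± 0.84) and the gastric mucin Muc6 (-6.86 ± 1.20). Apc was at 112 ± 19.6 and 95.3 ± 15.2 CPM (-0.23 ± 0.09, adjusted p = 0.045). This call ended without any 1 of 21 libraries (adjusted p = 0.051 to 0.087; replicates 2, 3, 5, 6 and 8 to 12 of wild-type and 4, 5, 7 to 15 and 17 of ex/ex tumours), and Apc stood at 0.07 with the lymphoid covariate. That covariate kept 1050 of the 5429 calls and ended that of Clec4e, and the position covariates ended that of Alb. Of 74 called genes named for this comparison (by that rule, or near Adam17), 46 kept their call with the lymphoid and 55 with the position covariates. Camera did not call the lists of ADAM17 regulators and related proteases (3 of 8 lower, 3 adjusted over the list alone; adjusted p = 0.19), shed ADAM17 substrates (1 of 17 higher and 3 lower, 1 and 3; 0.719) or enterocytes (1 of 24 higher, 0; 0.989). Neither did it call those of goblet (2 of 12 lower, 1; 0.719), Paneth (1 of 12 lower, 1; 0.963), tuft (1 of 12 higher and 2 lower, 1 and 2; 0.991) or enteroendocrine cells (0 of 15 past edgeR's threshold, 0; 0.79). With the lymphoid covariate, however, it called enterocytes (3.1e-09), enteroendocrine (0.0016), goblet (0.0117) and Paneth cells (0.0395) higher, with adjusted p = 0.427, 0.492, 0.661 and 0.661 with an estimated correlation. It then called the IL-6 family (0.00834), inflammatory (0.0179) and macrophage (0.0246) lists lower and the clock list higher (0.0491), with adjusted p = 0.379, 0.554, 0.636 and 0.603 with an estimated correlation. It no longer called stem cells (0.171), the EGFR family (0.59) or STAT3 response (0.255).

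**Figure D4:**
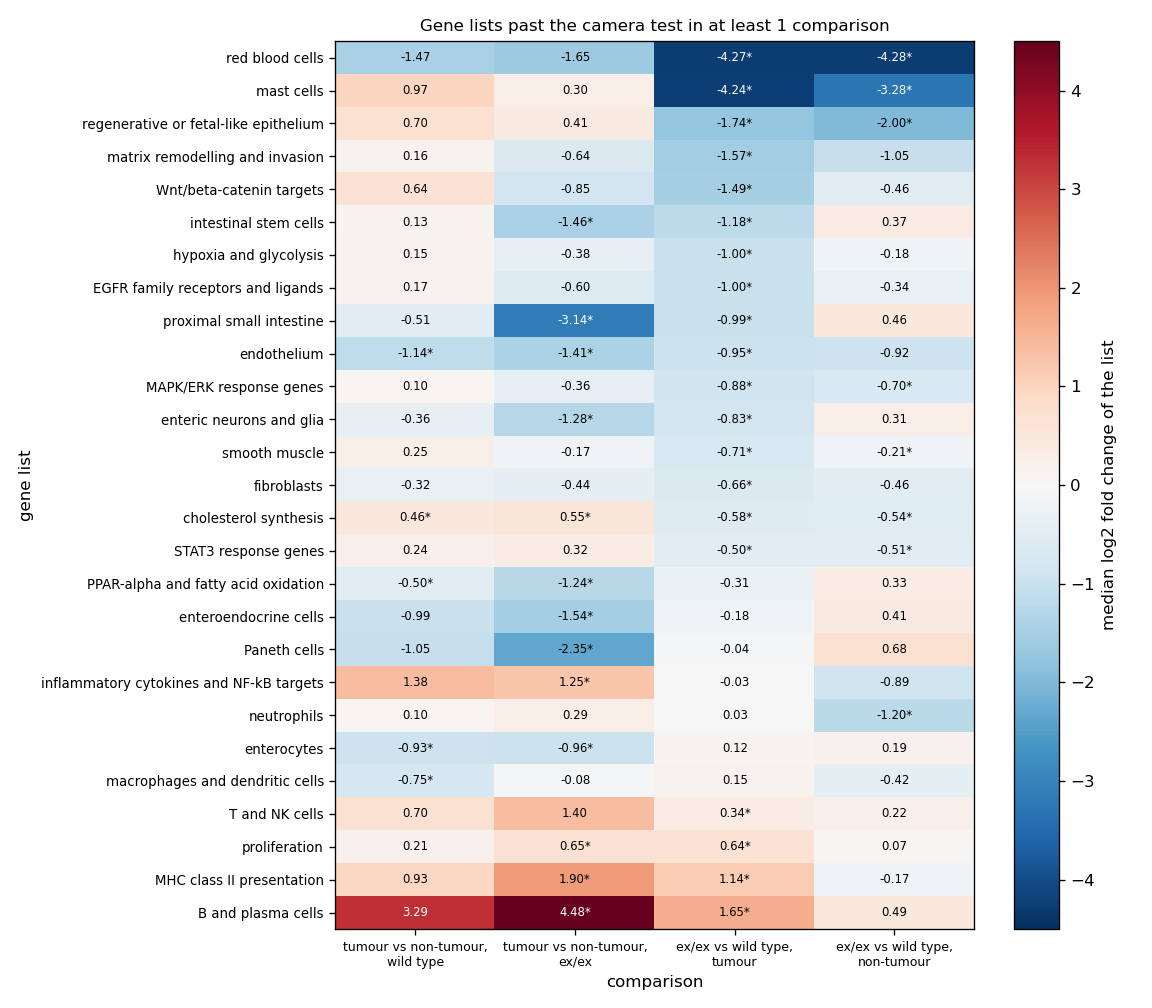
Median log2 fold change of 27 gene lists (vertical axis) in 4 comparisons (horizontal axis), on a colour scale with the value in each cell and an asterisk where camera with a preset correlation called the list; with all 39 libraries no call held with an estimated correlation. In ex/ex against wild-type tumours the medians ran from -4.27 for red blood cells to 1.65 for B and plasma cells.

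In non-tumour tissue the comparison asked how the genotypes differ outside tumours, and Socs3 was lower in ex/ex, at 37.4 ± 3.96 CPM in wild type (n = 4) and 11.4 ± 1.64 CPM in ex/ex (n = 6; -1.72 ± 0.18, adjusted p = 1.1e-07). Mesothelin (Msln, -5.10 ± 0.71), Il33 (-2.08 ± 0.38) and the protease inhibitor A2m (-7.48 ± 0.85) were also lower in ex/ex. Cyp1a1 rose from 3.11 ± 2.31 to 62.8 ± 38.4 CPM, Tmem252 from 7.36 ± 5.03 to 57.1 ± 18.2 CPM and the clock gene Arntl by 1.06 ± 0.23 (adjusted p = 0.0070). The duodenal genes Akp3 (8.57 ± 1.5) and Tmprss15 (8.59 ± 1.75) and Nr0b2 (3.94 ± 0.81) were higher, and Tff2 averaged 6430 ± 15720 CPM in ex/ex, where 1 library reached 38530 CPM and the median was 12.9 CPM. Adi1 (1.05 ± 0.17) rose and the potassium channel gene Kcns3 (-1.55 ± 0.39) fell. These 2 genes were picked outside the naming rule, after their values were seen, because they lie near Adam17, and both moved the same way in tumours (0.97 ± 0.10 and -1.06 ± 0.24). Both lost their non-tumour call in a fit of only the 2 groups.

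In non-tumour tissue 65 genes were called higher and 167 lower in ex/ex. The calls were 86 in all without wild-type replicate 4, 391 without replicate 3 and 33 without replicates 1 and 4 together (30 of them shared). Camera called 8 lists. All 5 red blood cell genes were lower (5 adjusted over the list alone), as were 6 of 13 regenerative genes (8), 2 of 17 MAPK/ERK response genes (7) and 2 of 17 STAT3 genes (2). Their camera adjusted p-values were 2.9e-07, 2.8e-06, 2.9e-05 and 0.00106, and adjusted p = 0.189, 0.189, 0.439 and 0.207 with an estimated correlation. Without the shallow wild-type replicate 1 the red blood cell, regenerative and STAT3 lists each had an adjusted p = 0.0226 with an estimated correlation. The other lists were mast cells (0 of 10 lower by edgeR, 9 adjusted over the list alone), cholesterol synthesis (1 of 13, 4), neutrophils (0 of 9, 0) and smooth muscle (0 of 12, 0). Camera gave them adjusted p-values of 0.00154, 0.00407, 0.0261 and 0.0266, and adjusted p = 0.754, 0.754, 0.526 and 0.784 with an estimated correlation. The smooth muscle call ended without wild-type replicate 1 (0.116) and with the lymphoid covariate (0.135). Without that replicate camera also called as lower the Wnt (0.00838), matrix (3.2e-04), fibroblast (0.00484), endothelial (0.0263) and hypoxia (0.00438) lists, with adjusted p = 0.665, 0.427, 0.617, 0.665 and 0.617 with an estimated correlation. With the covariate it called as lower the IL-6 family (0.0376), class II (0.00627) and macrophage (0.00576) lists, and as higher the stem cell (0.0213), goblet (0.0391), enteroendocrine (0.0213) and tuft cell (0.0399) lists. These 7 had adjusted p = 0.651, 0.701, 0.701, 0.701, 0.722, 0.701 and 0.721 with an estimated correlation. Without wild-type replicate 4, the library rich in vessel and blood genes, 0 of the 5 red blood cell, 2 of the 6 regenerative, 0 of the 2 MAPK/ERK and 1 of the 2 STAT3 genes still fell. The EGFR family (10), Wnt (21) and IL-6 family (11) lists had 0 members past edgeR's threshold, and 0 adjusted over the list alone. Apc was at 162 ± 18.2 and 148 ± 16 CPM (-0.12 ± 0.16, adjusted p = 0.95).

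The calls of Socs3, Msln, Il33, A2m, Akp3, Tmprss15, Cyp1a1 and Tmem252 held without any 1 library. In a fit of only the 2 groups, however, those of Il33 (adjusted p = 0.058), Akp3 (0.29), Tmprss15 (0.29) and Cyp1a1 (0.070) ended, and without wild-type replicates 1 and 4 those of Il33 (0.19), Akp3 (0.092), Tmprss15 (0.092) and Tmem252 (0.17). Other genes were called lower but lost the call without wild-type non-tumour replicate 4: Hbb-bt (-4.89 ± 0.70; -2.25 without it, adjusted p = 0.088), Hbb-bs (-4.04 ± 0.71; -1.56, 0.48), Hba-a1 (-4.28 ± 0.76; -1.92, 0.47), and Il1rn (-2.74 ± 0.57; -1.20, 0.72). So did Saa3 (-3.45 ± 0.81; -1.21), Cxcl5 (-3.95 ± 0.90; -2.19, 0.69), Etv4 (-3.00 ± 0.76; -1.67, 0.77) and Dusp4 (-1.66 ± 0.43; -0.91, 0.81). Arntl (0.99, 0.063) and Nr0b2 (3.44, 0.054) lost theirs there too. So did Lss (-0.89 ± 0.22; -0.68, 0.39), Retnlb (-5.79 ± 1.39; -2.77, 0.91), Anxa8 (-6.94 ± 1.71; -5.30, 0.29) and Kcns3 (-1.46, 0.18). These 4, Etv4 and Dusp4 also lost their calls without single libraries of ex/ex non-tumour tissue, and Kcns3 without wild-type replicate 2 (0.058). The call of Tff2 (12.63 ± 3.17) ended without any 1 of wild-type replicates 1 to 4 or ex/ex replicate 4 (3.38 without the last, adjusted p = 0.55). Of 26 called genes named for non-tumour tissue (Adi1, Kcns3 and those of the rule), 5 kept their call without wild-type replicates 1 and 4. The fit of the 2 groups tested 21 of them and kept 3 calls.

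The interaction asked whether the tumour change differed between genotypes. Socs3 stood at 37.4 ± 3.96 CPM in wild-type non-tumour tissue and 44.3 ± 9.13 in wild-type tumours, against 11.4 ± 1.64 and 27.9 ± 5.67 in ex/ex, a difference of the tumour changes of 1.06 ± 0.21 (adjusted p = 0.024). Stra6, a receptor for retinol uptake, averaged 11.4 ± 16.2 and 48.7 ± 21.9 CPM in wild type and 0.230 ± 0.160 and 38.6 ± 18 CPM in ex/ex (5.51 ± 0.81), and A2m differed by 6.80 ± 0.91. Msln (4.14 ± 0.79), Aldh3a1 (4.84 ± 0.96), the desmosomal gene Dsc3 (4.5 ± 0.88) and Sema4f (3.31 ± 0.62) had a higher tumour change in ex/ex. Pdx1 (-7.54 ± 1.57), Akp3 (-7.92 ± 1.53), the stem cell gene Lrig1 (-1.38 ± 0.31) and the gastric-type genes Tff2 (-15.47 ± 3.47), Muc6 (-13.51 ± 3.04) and Gkn3 (-12.11 ± 2.75) had a lower one.

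By edgeR 33 genes passed for the interaction (14 positive, 19 negative), with 2280 at an unadjusted p under 0.05. Camera called 6 lists, each with adjusted p = 0.83 with an estimated correlation. Stem cells (median difference -1.88, 1 of 12 past edgeR's threshold, 8 adjusted over the list alone; camera adjusted p = 1.0e-04) and Wnt targets (-1.39, 0 of 21, 12 adjusted over the list alone; 0.00338) were lower in the tumour change of ex/ex, as were enteric neurons and glia (-1.06, 0 of 12, 0 adjusted over the list alone; 0.0372). MHC class II (1.26, 0 of 9, 0; 1.8e-05), B and plasma cells (1.02, 0 of 14, 0; 0.00777) and T and NK cells (0.52, 0 of 15, 0; 0.043) were higher. Without the shallow wild-type non-tumour replicate 1 camera no longer called the neural (0.0683) and T and NK cell (0.0594) lists. With the lymphoid covariate the neural (0.33), T and NK cell (0.952) and B and plasma cell (0.522) calls ended. The same replicate left out brought calls of proliferation (0.00627), proximal (0.0107) and PPAR-alpha genes (0.0135), and the covariate brought calls of enterocyte (8.7e-04) and clock genes (0.0205). Of these 5 lists the first 3 had adjusted p = 0.753 and the last 2 adjusted p = 0.997 with an estimated correlation. The number of calls was 1 (A2m) without wild-type non-tumour replicates 1 and 4, 6 without replicate 1 and 52 without replicate 4. It was 10 and 56 without ex/ex non-tumour replicates 4 and 6, 65 and 108 without wild-type tumour replicates 1 and 4, and 17 to 21 without wild-type tumour replicate 2, 3, 8, 9, 10 or 12 or ex/ex tumour replicate 4, 5, 6, 8 to 13, 15 or 17. A2m and Stra6 held without any 1 library. Without wild-type non-tumour replicate 4 the adjusted p was 0.057 for Msln and Socs3, 0.17 for Sema4f, 0.13 for Aldh3a1 and 0.070 for Dsc3. Socs3 also missed the threshold without wild-type replicate 1 (0.053) or ex/ex replicate 4 (0.064) of non-tumour tissue. Akp3 missed it without wild-type replicate 1 (0.092) and Pdx1 without wild-type replicate 1, 2 or 3 or ex/ex replicate 4 (0.086 to 0.096). Lrig1, Tff2, Gkn3, Muc6 and Rap1b (0.93 ± 0.21), near the threshold, each lost the call without any 1 of 22 to 27 libraries (0.051 to 0.35). Without ex/ex non-tumour replicate 4 the differences of Tff2, Muc6 and Gkn3 were -6.22, -4.84 and -4.24 (adjusted p = 0.31, 0.34 and 0.35). Pnck (5.88 ± 1.12) and mt-Rnr2 (3.81 ± 0.81) rested on the library labelled wild-type non-tumour replicate 1, without which they stood at -1.32 and 0.21. Of 16 called genes named for the interaction, 9 kept the call with the lymphoid and 4 with the position covariates. By voom without sample weights 1 did, without a count filter 10, with DESeq2's size factors 15 and with the Xist covariate 16. Socs3 lost its call with either kind of covariate, without a count filter and by voom without weights.

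The tumour changes of both genotypes, which share no library, were related across the 16327 genes (Pearson's r 0.675, Spearman's rho 0.627; genes are not independent replicates). Of the calls, 218 genes were higher in both (73.8 for independent lists), 411 lower in both (119.9) and 2 went opposite ways. Within 20 Mb of Adam17, 53 of 131 tested genes (40.5%) differed between ex/ex and wild-type tumours, against 33.2% of other genes (odds ratio 1.37, 95% interval 0.945 to 1.97; 2-sided Fisher's exact p = 0.093). Within 10 Mb the odds ratio was 1.94 (95% interval 1.10 to 3.42, exact p = 0.015). For the calls of non-tumour tissue within 20 Mb it was 2.80 from 5 called genes, with a 95% interval of 0.886 to 6.81 that includes 1 (exact p = 0.039). Without wild-type non-tumour replicate 1 that odds ratio was 3.87, with an interval of 1.22 to 9.45 that excludes 1 (exact p = 0.012). With the lymphoid covariate it was 1.03 in tumours (exact p = 0.91; 19.1% against 18.6%).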

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

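The tests of lymphoid content as the whole cause, of adenoma epithelium, of lymphoid follicles, of genotype as their only source and of position were chosen only after the results they bear on were seen; the dilution test and the splits of the samples were not.

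Of 88 combinations of group and measure in groups of 4 to 6 libraries, 15 had 1 library further from the others than Dixon's 95% limit allows, where chance gives about 1 in 20. Wild-type non-tumour replicate 1, the shallow library, stood apart in mitochondrial share (21.1% against 2.63 to 3.78%), and Gm42418 share (34.8% against 0.104 to 2.34%). It also stood apart in the mean log2 CPM of stem cell (3.02 against 4.84 to 4.96), goblet (3.69 against 7.32 to 7.61), tuft (0.84 against 3.01 to 3.13) and neural and glial genes (-0.45 against 1.77 to 1.88). Wild-type non-tumour replicate 4 stood apart in MAPK/ERK response (4.53 against 3.27 to 3.49), endothelium (6.52 against 3.59 to 3.92) and red blood cell genes (7.38 against 2.61 to 3.14). In ex/ex non-tumour tissue, replicate 3 stood apart in Gm42418 share (0.357% against 0.142 to 0.202%), replicate 4 in enteroendocrine genes (3.28 against 3.93 to 4.25), and replicate 5 in immediate early and heat shock genes (4.27 against 3.73 to 3.85). There replicate 6 stood apart in interferon response (3.32 against 4.09 to 4.5), fibroblast (6.26 against 5.12 to 5.53) and PPAR-alpha genes (6.07 against 6.79 to 7.16).

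The interaction test set these genes apart, with a log2 tumour change in ex/ex minus that in wild type of 6.80 (A2m), 5.51 (Stra6), 4.84 (Aldh3a1), 4.5 (Dsc3), 4.14 (Msln), 3.31 (Sema4f), 1.06 (Socs3), -7.92 (Akp3), -7.54 (Pdx1), -1.38 (Lrig1), 5.88 (Pnck), 3.81 (mt-Rnr2), -12.11 (Gkn3), -13.51 (Muc6), -15.47 (Tff2) and 0.93 (Rap1b). Without ex/ex non-tumour replicate 4 those of Gkn3, Muc6 and Tff2 were -4.24, -4.84 and -6.22, and without wild-type non-tumour replicate 1 those of Pnck and mt-Rnr2 were -1.32 and 0.21. For lists the median difference was -1.39 (Wnt targets), -1.88 (stem cells), 1.26 (MHC class II), 1.02 (B and plasma cells), 0.52 (T and NK cells) and -1.06 (enteric neurons and glia). Camera called none of these lists with an estimated correlation. With the lymphoid covariate the calls of B and plasma cells, T and NK cells and neural genes ended (camera adjusted p = 0.522, 0.952 and 0.33).

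Chance was tested with 100 splits of the same libraries into groups of the same sizes, the real split included. The splits treat each library as independent, so they cannot exclude chance where libraries share an animal. Under that assumption chance was excluded for tumour against non-tumour tissue in ex/ex (1 split as large, 7685 calls, highest other 141). The same held for the genotypes in non-tumour tissue (1 split, with 65 higher and 167 lower calls, highest other 180). It also held for the genotypes in tumours (2 splits, 5429 calls, highest other 6391). There a split above the real count points to a structure of the samples other than genotype. Chance was not excluded for tumour against non-tumour tissue in wild type (5 splits; 825 calls, highest other 5179, which again points to a structure of the samples) nor for the interaction (7 splits; 33 calls, highest other 224).

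Wnt targets were lower in ex/ex than in wild-type tumour libraries (median -1.49 over 21 genes). Dilution of the epithelium by lymphoid cells would lower all epithelial genes alike, but the Wnt median lay 0.87 below that of 12 pan-epithelial markers (difference -0.87, medians -1.49 and -0.62, 1-sided permutation p = 0.013 over genes). This p-value measures the spread over genes and not between libraries. The Wnt list is not purely epithelial: Lef1 (0.10) and Tcf7 (0.38) are also expressed by T cells. Lymphoid content as the whole cause was tested with the lymphoid covariate, where 10 of the 16 Wnt targets that fell still fell. The median of the 16 went from -2.08 to -0.94 and their median SE from 0.33 to 0.39. The calls lost thus went with smaller changes as well as a larger error. The covariate is an imperfect measure of lymphoid content, so the calls that remain cannot exclude this cause. Little adenoma epithelium in the ex/ex tumour libraries stays open: against non-tumour tissue of ex/ex their Wnt targets stood at -0.85 and pan-epithelial markers at -0.42 (difference -0.43; 1-sided permutation p for higher Wnt targets 0.96), while in wild type the difference was 0.24 (permutation p = 0.14). An effect of the ex allele on Wnt target genes in tumour cells, which the design names, also stays open and cannot be weighed without the share of tumour cells in each library.

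Lymphoid follicle genes were high in ex/ex tumour libraries. Sampled lymphoid follicles with their covering epithelium are a candidate explanation, since 5 of 6 genes of follicle-associated epithelium were higher in ex/ex tumour than non-tumour libraries (Spib 4.43, Sox8 4.35, Ccl20 2.20, Gp2 2.03 and Tnfaip2 1.35; Ccl9 stood at -0.32), as were 8 of 8 genes of germinal centres and follicle stroma, such as Cxcl13 (6.05). The ex/ex genotype as the only source is argued against by 3 wild-type tumour libraries (replicates 1, 4 and 7) with over 3 times the Cd79a of the highest non-tumour library (25.8 CPM). Immune cells drawn to ex/ex tumours stay open and were not tested; B cells also express Spib.

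Tumour and non-tumour libraries differed in genes of position along the small intestine. Non-tumour tissue of ex/ex taken nearer to the stomach than the tumours may account for this: 3 of 3 proximal transcription factors were lower in ex/ex tumours, by over 1 log2 unit more than the pan-epithelial median of -0.42 (Gata4 -1.61, adjusted p = 0.021; Pdx1 -7.93, 6.0e-09; Onecut2 -3.51, 1.1e-04). In wild type they stood at -1.09, -0.39 and -0.51 (adjusted p = 0.39, 0.88 and 0.80). The ileal gene Fabp6 was also higher in wild-type tumours (8.72 ± 2.66, adjusted p = 0.047). That call ended with the position covariates, which were made in part from Fabp6 itself. The labels give no position, and a loss of proximal identity in tumours stays open. Genes of position also differed between the genotypes. In ex/ex against wild-type tumours Gata4, Pdx1 and Onecut2 stood at -0.36, -3.94 and -2.58 (adjusted p = 0.59, 1.8e-04 and 9.8e-04). In non-tumour tissue Akp3 (8.57) and Tmprss15 (8.59) were higher in ex/ex, while 0 of 9 proximal genes passed edgeR's threshold. A difference in position between the genotypes thus stays open and limits those comparisons and the interaction.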

How the results depend on the processing

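The tests with the lymphoid or position covariates, limma-voom without sample weights, those leaving out both replicates 1 and 4 of wild-type non-tumour tissue, and the list tests, odds ratios and relation of tumour changes without its replicate 1 were chosen only after the results were seen; the other alternatives were planned, among them the counts of calls leaving out each library in turn. For tumour against non-tumour tissue in wild type (825 calls) there were 434 with a log2 fold change of at least 1, 6126 by limma-voom with quality weights (weights from 0.085 to 5.31), 480 by voom without weights, 447 without a count filter, 197 in a fit of the 2 groups, 1651 with the lymphoid covariate, 1524 with position, 1637 with both, 461 leaving out both libraries, and 494 (without wild-type non-tumour replicate 2) to 935 leaving out each library. In ex/ex (7685) these were 3568 (fold change), 11797 (quality weights), 3077 (lymphoid), 2486 (position), 3024 (both covariates) and 6794 to 8559 (each library). For the genotypes in tumours (5429) they were 2030, 11850, 3045, 2849 (position) and 4396 to 7464. In non-tumour tissue (65 higher and 167 lower) they were 1597 (quality weights), 86 (voom), 134 (stricter filter), 25 (2 groups), 449, 602 and 556 (covariates), 33 leaving out both libraries, and 86 (without wild-type replicate 4) to 391 (without wild-type replicate 3). For the interaction (33) they were 133 (DESeq2), 8459 (quality weights), 1 (voom), 15 (no filter), 13 (stricter filter), 8 (position), 1 leaving out both libraries, and 6 (without wild-type non-tumour replicate 1) to 108 (without wild-type tumour replicate 4). The other settings kept these counts within 1.5 times. Lists called (5, 13, 20, 8 and 6) were 0 with an estimated correlation in each contrast (but 3 for the genotypes in non-tumour tissue without the shallow replicate 1: red blood cells, regenerative epithelium and STAT3 response, each at an adjusted p of 0.0226), 0, 1 and 1 by fry for tumour tissue in wild type, the genotypes in non-tumour tissue and the interaction, and 14 with the lymphoid covariate for the genotypes in non-tumour tissue. The odds ratio near Adam17 (1.37) was 1.94 within 10 Mb, 2.80 for the calls of non-tumour tissue, 3.87 for these without replicate 1, 1.34 for tumours without replicate 1 and 1.03 with the lymphoid covariate. Adam17 kept its direction and call in each setting, from -1.63 to -1.02 in tumours and -2.29 to -1.91 in non-tumour tissue, and leaving out each library gave -1.25 to -1.09 and -2.29 to -1.91. The relation of the tumour changes (0.675) was 0.745 over called genes and 0.690 without replicate 1. Signs turned, in ex/ex against wild-type tumours, for Apc (0.071 lymphoid, 0.078 both covariates), Tgfa (0.35 lymphoid, 0.34 position, 0.47 both), Mzb1 (-0.25 lymphoid, -0.25 both) and Mki67 (-0.13 lymphoid, -0.15 both). They turned in wild-type tumours against non-tumour tissue for Kdr (0.15 leaving out both libraries, 0.11 without replicate 4, -2.60 to 0.11 leaving out each library), Vwf (0.064 leaving out both) and Pnck (0.56 and 0.35 by voom with and without weights, 0.48 leaving out both, 0.78 without replicate 1, -6.86 to 0.78 leaving out each library), in ex/ex for Fabp6 (-0.77 with both covariates), and in the interaction for Pnck (-0.27, -0.60, -1.01 and -1.32 in the same order, -1.32 to 6.34 leaving out each library). Over the 200 gene results named (Adi1 and Kcns3 outside the naming rule), 6240 values kept direction and call, 724 lost the call, 17 gained it and 21 turned. The lymphoid covariate shared 1801 of 7685 and 1050 of 5429 calls. The cause was not tested, except that a minimum change can only leave fewer calls; leaving out libraries gave fewer or more. At its depth, replicate 1 of wild-type non-tumour tissue limits genes of low abundance. No paired analysis was possible because the labels name no animal and replicate numbers were given in accession order.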

Other observations

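The genes in the last paragraph were chosen and their values compared only after the data were seen.

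Camera did not call interferon response genes between ex/ex and wild-type tumours (2 of 17 rose by edgeR, 0 adjusted over the list alone; adjusted p = 0.215), nor macrophage and dendritic cell genes (2 of 14 rose and 4 fell, 2 and 4 adjusted over the list alone; 0.571, but lower with the lymphoid covariate at 0.0246, and adjusted p = 0.636 with an estimated correlation) or neutrophil genes (1 of 9 rose and 4 fell, 1 and 4; 0.719). It did not call circadian clock genes (2 of 14 rose and 3 fell, 2 and 4; 0.902, but higher with that covariate at 0.0491, and adjusted p = 0.603 with an estimated correlation) or PPAR-alpha genes (1 of 12 rose and 4 fell, 1 and 4; 0.0661). Colon genes (2 of 5 fell, 2; 0.256), adipocyte genes (3 of 5 fell, 3; 0.0661) and immediate early and heat shock genes (1 of 12 rose and 4 fell, 1 and 5; 0.109) were not called by camera either.

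Leaving out wild-type non-tumour replicate 1, 13 genes separated the 15 wild-type from the 23 ex/ex libraries of both tissues with means at least 8 times apart and the higher mean at least 2 CPM. Of these, 5 were higher in ex/ex and 8 in wild type, 5 are annotated as pseudogenes and 4 lie on chromosome 17. Gm6472 (chromosome X, 152909505 to 152910155 in GRCm38) had a mean of 0.0754 CPM in wild type and 63.3 CPM in ex/ex (29.5 to 97.0), and Gm10093 had 0.0605 and 8.95, Gm7809 0.0284 and 3.76, Gm10282 0.460 and 5.59, and Gm20379 0.0835 and 2.20 CPM. Higher in wild type were Gm9825 (4.12 and 0.0217 CPM), Atp6v0c-ps2 (6.64 and 0.0516), Hbb-bt (24.8 and 1.13), Hbb-bs (103 and 5.84), Hba-a1 (26.4 and 1.28), Hmga1b (2.26 and 0.0407), Prss41 (2.82 and 0.255) and Capn11 (5.69 and 0.234). Pseudogenes and retrocopies share reads with their parent genes, so their values are uncertain. Protein-coding genes such as Prss41 and Capn11 also separated the genotypes. The globin genes Hbb-bt, Hbb-bs and Hba-a1, on chromosomes 7 and 11, belong to the red blood cell list. They may follow the blood in a sample, so they say little about the genome. The 13 genes lie on chromosomes 6, 7, 8, 11, 13, 17 and X, while Adam17 lies on chromosome 12. Whether the genotypes differ in other parts of the genome was not tested, which limits each comparison of ex/ex with wild type.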
